A study of Cucumis sativus with 4 samples.

How the data were processed

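Total RNA of cucumber (Cucumis sativus) female buds was extracted with Trizol and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The series describes profiles of leaves as well; leaf samples are not analysed here. The 4 libraries were grouped by their titles into WT replicates 1 and 2 and rl replicates 1 and 2.

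Per the submitters' processing notes, HISAT (a spliced aligner) and HTSeq (a counter of reads per gene) were used; their versions, the genome build, the annotation and whether counting used strand are not given in the sources used here. Genes that overlap or share reads with a near-identical copy cannot be recognised without that annotation, so any single gene could be affected. The authors deposited 1 table of CPM values for 17480 genes. The CPM values are relative to the reads on the listed genes, since each deposited column sums to 1000000. Every listed gene had at least 1.01 CPM in at least 2 of the 4 libraries, so genes with lower levels are not analysed here. No row lacked a gene identifier. The order of the rows closely followed the rank of edgeR's p for the genotype comparison (Spearman correlation across genes 0.978).

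In each library 100% of the values were whole multiples, within 1e-06 reads, of the smallest value above 0, so whole reads could be recovered. They came to 17792057 and 17549219 reads for the WT libraries and 18345095 and 18097164 for the rl libraries. At this depth 3 reads correspond to 0.164 to 0.171 CPM. Read counts differed between any 2 libraries by far more than sampling noise (chi-square per degree of freedom 22.7 for the 2 WT and 47.1 for the 2 rl libraries). Each was kept as a separate replicate. This comparison is with counting noise alone, so it does not tell whether the libraries came from separate plants.

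The main test, fixed before the data were examined, was limma 3.58.1 (R 4.3.3) on log2(CPM + 1) with a mean-variance trend in eBayes, two-sided, over all 4 libraries with genotype as the only term, and Benjamini-Hochberg adjustment at 0.05. The planned filter of 1 CPM in 2 libraries removed no gene. As alternatives, edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 were run on the recovered reads, which they need. Others were pseudocounts of 0.25 and 5 CPM, a filter of 5 CPM in 2 libraries, rescaling by the median of ratios, quantile normalization, eBayes without trend or with robust estimation, the replicate number as a block, a 2-fold minimum, an adjusted p of 0.10, and leaving out each library. With 1 library left in a genotype, that library was assumed to vary like the pair in the other genotype.

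The genes named in the text followed a rule fixed before the data were examined. Because no source used here pairs the identifiers with names, at most 2 each way are printed. Lower in rl, these are the 2 with the largest fall on the log2(CPM + 1) scale among genes that passed, with at least 5 CPM in the higher genotype and no overlap between genotypes. By the ratio of mean CPM, unnamed genes that passed fell further (43.4 and 40.4) than Csa3G127770 (30.1). No gene passed in the other direction, so the 2 with the smallest limma p were taken. For the same reason the 33 gene lists fixed beforehand (auxin, ovule, floral, hormone, cell wall, other tissues, stress) could not be formed, and their camera tests were not run. Markers of other tissues and of RNA quality were among them, so differences in tissue makeup or RNA quality between libraries were not checked.

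The 3 tests were tested on simulated data: negative binomial counts for all 17480 genes with the real means, library sizes and edgeR's dispersions, and 200 changed genes. limma called 12 unchanged genes, edgeR 12 and DESeq2 41. Clustering along the chromosomes was tested by sorting genes by identifier, marking 430 genes and counting them in sliding windows of 50 genes, against 10000 permutations of gene order within chromosomes.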

Results

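The expression of genes was measured by RNA sequencing in female flower buds of cucumber plants of 2 genotypes, wild type (WT) and round leaf (rl), with 2 libraries each and 4 in all. The study's title ties the work to CsPID, a cucumber gene named after PINOID, the plant protein kinase that directs polar auxin transport through PIN efflux carriers, and to the formation of lateral organs. The plants were grown in a greenhouse and received no treatment, and genotype is the only factor that the labels give as different. The labels give no stage of the buds, so other differences may run along with genotype. Each library held between 17549219 reads (WT replicate 2) and 18345095 reads (rl replicate 1) over the 17480 genes listed, so that 1 read was worth between 0.0545 and 0.0570 counts per 1000000 reads (CPM). The 10 most abundant genes took 2.09% to 2.81% of the reads of a library. The labels do not say whether the 2 libraries of a genotype came from separate plants, so the p-values below measure only the spread between these libraries, which may be technical.

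The genes could be followed only by their identifiers. The table pairs no identifier with a gene name or a function, and 0 of the 17480 identifiers matched the RefSeq gene table used here. The level of CsPID in each library, and the behaviour of auxin, ovule, floral or hormone genes as groups, are therefore not analysed here. In what follows the first digit of an identifier is read as the chromosome, as is usual for cucumber genes of this form.

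The libraries of the 2 genotypes were close to one another over the whole set of genes. The 2 WT libraries had the highest agreement of any pair, with a Pearson correlation of log2(CPM + 1) across genes of 0.984, and 269 genes (1.54%) stood at least 2-fold apart between them. The 2 rl libraries were less alike, with a correlation of 0.970 and 670 genes (3.83%) at least 2-fold apart. Pairs made of a WT and an rl library had correlations of 0.965 to 0.978, and WT replicate 2 with rl replicate 2 had fewer genes at least 2-fold apart (499) than the 2 rl replicates had. The first principal component, with 46.7% of the variance, placed the WT libraries at -32.7 and -14.3 and the rl libraries at 25.8 and 21.1. The second, with 37.6%, separated the 2 rl libraries (30.0 and -30.0).

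The comparison of rl with WT asks which transcripts differ in female buds of the mutant. Expression of 5 genes fell in rl and of 0 genes rose, at an adjusted p below 0.05 in the limma test. The most strongly reduced was Csa6G526550, on chromosome 6, which went from 40.3 ± 12.6 CPM (SD, n = 2) in WT to 0.356 ± 0.113 CPM (SD, n = 2) in rl, a ratio of mean CPM of 113. It was covered by 876 and 552 reads in the WT libraries and by 8 and 5 reads in the rl libraries. Csa3G127770, on chromosome 3, was the most abundant of the 5 in WT and fell from 145 ± 34.9 CPM to 4.83 ± 0.109 CPM (SD, n = 2 each), a ratio of 30.1. The other 3 genes fell from 23.3 ± 5.06 to 0.578 ± 0.277 CPM (on chromosome 1), from 19.03 ± 2.50 to 0.438 ± 0.151 CPM (on chromosome 3) and from 50.4 ± 7.87 to 7.05 ± 0.0486 CPM (on chromosome 6), SD with n = 2 in each case.

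On the log2(CPM + 1) scale, which understates the change of low genes, Csa6G526550 fell by 4.90 (SE 0.27, limma adjusted p = 0.0227) and Csa3G127770 fell by 4.63 (SE 0.20, limma adjusted p = 0.0118). The other 3 had log2 changes of -3.94, -3.80 and -2.67, with limma adjusted p of 0.0275, 0.0227 and 0.0275. The same 5 genes were the only ones called by edgeR's quasi-likelihood test on the recovered reads. DESeq2 on the same reads called these 5 among 291 genes, of which 192 were lower and 99 higher in rl. None of the 5 passed in limma without WT replicate 1, when 0 genes were called, although the log2 changes of Csa6G526550 (-4.58) and Csa3G127770 (-4.38) stayed close to those with all libraries. In limma 2 of the 5 passed without WT replicate 2, when 3 were called. Without rl replicate 1 and without rl replicate 2 the log2 changes were -4.98 and -4.81 for Csa6G526550. For Csa3G127770 they were -4.65 and -4.61. With 1 library left in a genotype, the spread came only from the other genotype's pair. The WT pair was more alike than the rl pair (269 against 670 genes at least 2-fold apart). Numbers of calls without a WT library and without an rl library are therefore not comparable.

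**Figure D1:**
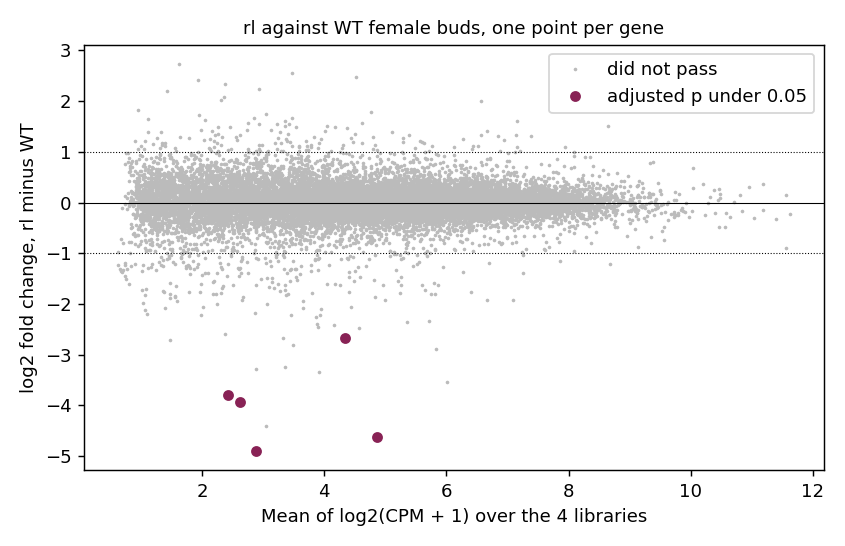
Log2 fold change of rl over WT on the log2(CPM + 1) scale (vertical axis) against mean log2(CPM + 1) over the 4 libraries (horizontal axis), with 1 point per gene and dotted lines at 2-fold. The 5 genes that passed the limma test (large points) all lie below the lower dotted line, between -2.67 and -4.90.

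No gene passed in the direction of higher expression in rl, and edgeR also called 0 genes there. At an unadjusted limma p below 0.05 there were 640 higher and 753 lower genes, against 874 in all that chance gives. The same unadjusted cutoff gave 699 higher and 717 lower genes in edgeR, and 654 higher and 637 lower in DESeq2. Without rl replicate 2 limma called 59 higher genes, and without rl replicate 1 it called 4. The 2 genes nearest to the threshold that were expressed at 5 CPM or more were Csa1G618390 and Csa6G006890. Csa1G618390, on chromosome 1, was barely detected in WT, with 2 and 5 reads (0.199 ± 0.122 CPM), and measured 6.99 ± 1.14 CPM in rl (SD, n = 2 each), a log2 difference of 2.73 (SE 0.24, limma adjusted p = 0.0778). Csa6G006890, on chromosome 6, measured 60.8 ± 4.81 CPM in WT and 164 ± 0.377 CPM in rl (SD, n = 2 each), a log2 difference of 1.42 (SE 0.13, limma adjusted p = 0.0778). DESeq2 called both, and limma called both without rl replicate 2 (adjusted p = 0.0319 and 0.0302).

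**Figure D2:**
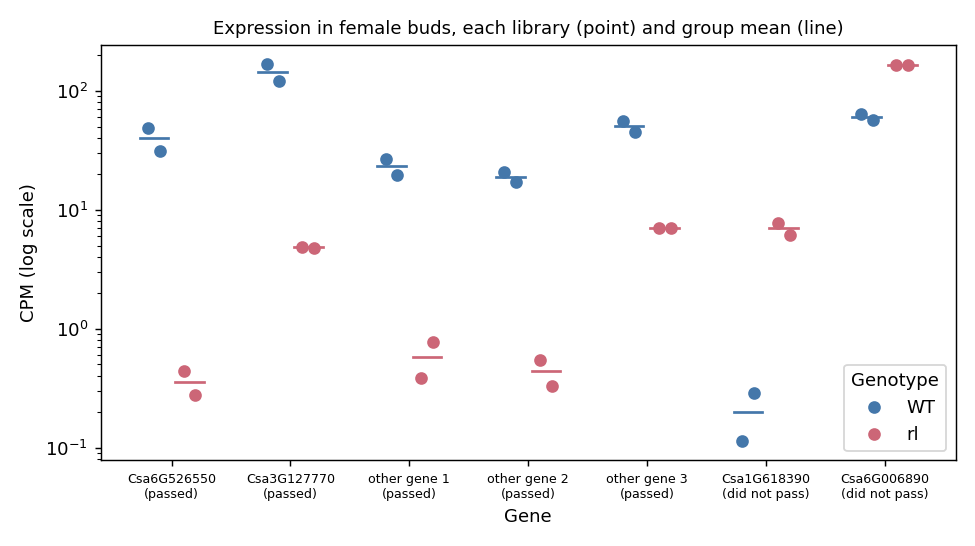
CPM on a log axis for the 5 genes that fell in rl and the 2 named genes that were higher in rl without passing the test, with 1 point per library and a line at the mean of the 2 libraries of a genotype. In every gene shown the 2 WT points and the 2 rl points do not overlap, which the rule for the named genes required. Csa6G526550 drops from 31.5 CPM or more in WT to 0.436 CPM or less in rl.

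Beyond these genes, larger differences were more often toward lower than toward higher levels in rl. With no overlap between the genotypes, 230 genes were at least 2-fold lower and 124 at least 2-fold higher on the log2(CPM + 1) scale. That scale understates the change of low genes: Csa1G618390 was 35.2-fold higher in rl by the ratio of mean CPM. At 4-fold the numbers on the log2(CPM + 1) scale were 34 lower and 9 higher, and at 8-fold 9 and 0. This excess was not kept without WT replicate 1 (196 lower and 178 higher) or without rl replicate 2 (330 lower and 336 higher). It was kept without WT replicate 2 (365 lower and 230 higher) and without rl replicate 1 (315 lower and 243 higher). By abundance, genes with a mean of 50 CPM or less held most of them, with 83 lower and 37 higher among the 2728 genes under 5 CPM, 123 and 70 among the 9179 genes from 5 to 50 CPM, and 24 and 17 among the 5573 genes over 50 CPM. At 2 libraries against 2, chance alone leaves 33.3% of genes without overlap. The share was 39.5% between the genotypes, 35.3% for the split by replicate number and 25.2% for the remaining split. At any size of difference, 18.3% of genes were higher and 21.3% lower in rl without overlap. Direction was also uneven in the split by replicate number, with 20.5% higher and 14.8% lower in the libraries of replicate 2. In the remaining split it was nearly even (12.8% and 12.4%). A gene without ties is separated by exactly 1 of these 3 splits, so the shares are not independent of one another.

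A small group of transcripts was near or below detection in one genotype only. Of the genes with at least 1 CPM in both WT libraries, 17 had at most 3 reads in each rl library, and 9 of these had 0 reads in both. In the opposite direction 1 gene had at most 3 reads in each WT library and at least 1 CPM in both rl libraries. With rl set at 3 reads per library, the observed WT means of the 17 genes were 8.24-fold to 37.9-fold higher. The most abundant of the 17 measured 6.24 CPM in WT. None of these genes passed the limma test, and these ratios make no allowance for counting error or for the spread between libraries.

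Of all 17480 genes, the median standard error was 0.19 on the log2 scale, which gives a median 95% interval of 0.46 on either side of the estimate. Data were simulated with edgeR's dispersions and each gene drawn independently, so differences shared by many genes of a library were not simulated. In these data limma recovered 31.0% of 100 genes changed 2-fold, 88.0% of 50 changed 4-fold and 98.0% of 50 changed 8-fold. DESeq2 recovered more of them (54.0%, 92.0% and 100%), but it also called 41 unchanged genes where limma called 12. Of genes picked here for an observed difference on the log2(CPM + 1) scale without overlap, 5 of 354 passed at 2-fold or more. At 4-fold or more 5 of 43 passed, and at 8-fold or more 4 of 9. Genes picked in this way can include chance differences, since the other 2 splits of the libraries gave 181 and 75 at least 2-fold apart. The simulated folds were set on the counts, so these shares are not comparable with the simulated ones. The sensitivity of the real comparison is not known.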

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

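Counts of 5 genes, 0 of them higher in rl, were also obtained with pseudocounts of 0.25 and 5, a filter of 5 CPM in 2 libraries, median-of-ratios rescaling, quantile normalization, robust eBayes, a 2-fold minimum and edgeR, and 7 genes (2 higher) without the trend; the 5 genes were among the calls each time. Rescaling and quantile normalization placed the median log2 difference of all genes at 0.0021 and -0.0046, against -0.0092 without them. Removing the filter changed nothing, since the table was already filtered. A threshold of 0.10 called 28 genes (6 higher, 22 lower). DESeq2 called 291 (99 higher, 192 lower), and the reason was not tested. In the simulation DESeq2 called more changed and more unchanged genes than limma. Leaving out 1 library gave 0 to 125 genes: 0 without WT replicate 1, 3 without WT replicate 2, 32 (28 lower) without rl replicate 1 and 125 (66 lower) without rl replicate 2. With 1 library left in a genotype, the spread came only from the other genotype's pair, so these numbers are not comparable between the genotypes. The replicate block gave 117 genes (32 higher, 85 lower), the 5 among them. Replicate numbers are not stated to pair the libraries. Across genes, WT replicate 1 minus WT replicate 2 had a correlation of 0.18 with rl replicate 1 minus rl replicate 2. There were only 2 pairs. No direction reversed among the 4 named genes. They were picked without overlap between the genotypes, so leaving out a library or changing the pseudocount could not reverse them. Csa6G526550 and Csa3G127770 passed in 14 of 15 alternatives each, with log2 changes of -4.58 and -4.38 and adjusted p of 0.103 and 0.0874 in limma without WT replicate 1. Csa1G618390 and Csa6G006890 passed in 4 of 15 each, with adjusted p up to 0.381 and 0.383. Chosen after seeing the data, the counts of genes at least 2-fold apart were 311 lower and 202 higher with a pseudocount of 0.25, and 95 and 42 with a pseudocount of 5. The tests of gene lists, with an estimated correlation or by fry included, were not run, because no list could be formed.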

Other observations

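The tests of direction (rescaling included), chromosomes, windows and splits in this part, and the counts at an unadjusted p below 0.01, were chosen after seeing the data. Genes with an unadjusted limma p below 0.01 were spread over all 7 chromosomes. There were 430 of them (290 lower and 140 higher in rl), against 174.8 that chance gives. Their share ran from 1.81% of the genes of chromosome 7 (31 of 1713) to 2.91% of those of chromosome 3 (107 of 3676, 81 of them lower in rl). No chromosome stood apart by Fisher's exact test (lowest adjusted p = 0.282, 8 groups tested, the unplaced genes included), with genes taken as independent, which they are not. The lower genes outnumbered the higher ones on each of the 7 chromosomes.

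Neighbouring genes were then examined for one linked stretch of changed genes, which linked variants around a mutated locus may give. Ranked by limma p, the fullest window of 50 neighbouring genes lay on chromosome 6 and held 10 of the 430 genes, 8 lower and 2 higher in rl, with a permutation p = 0.0009 (0.0054 adjusted over 6 tests). Both other splits of the 4 libraries gave at most 7 (permutation p = 0.297 and 0.282). The 50 genes of this window had a median log2 difference of -0.07, with 35 lower and 15 higher in rl, and the 10 picked for their p had one of -0.84 (range -1.54 to 1.27). None of them passed the limma test singly (lowest adjusted p = 0.118). Ranked by size of change instead, the fullest window held 7 genes, on chromosome 1 (permutation p = 0.301). The difference between the 2 WT libraries, with no genotype in it, gave 8 (permutation p = 0.0392, 0.118 adjusted over the 6 tests). Differences of neighbouring genes were correlated in every contrast (0.0760 to 0.104). Permuting gene order removes this correlation, so the permutation p-values may be too small. Whether the genotypes differ over a linked stretch therefore stays open. A cluster of related genes that share reads or regulation was not tested.

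The excess of lower over higher genes among those at least 2-fold apart on the log2(CPM + 1) scale without overlap (230 of 354, 65.0%) was weighed against differences between libraries. Rescaling by the median of ratios left it at 63.6% (95% exact binomial interval 58.4% to 68.6%), which argues against scaling as its whole cause. Without WT replicate 1 it was 52.4% (47.2% to 57.6%), but without rl replicate 2 it was 49.5% (45.7% to 53.4%), and without WT replicate 2 and without rl replicate 1 it stayed at 61.3% (57.3% to 65.3%) and 56.5% (52.2% to 60.6%), so an effect of WT replicate 1 alone cannot be told apart from one shared with rl replicate 2, since leaving out a library also admits genes that differ by chance. Among the 196 genes picked as lower in rl without WT replicate 1, 67.3% (60.3% to 73.9%) were higher in WT replicate 1 than in WT replicate 2, although picking on WT replicate 2 pulls the other way. All binomial intervals in this paragraph take genes as independent, which they are not, so they do not measure the spread between libraries. For the lower genes a candidate explanation is a gradient between buds, such as their stage, that runs along the genotype difference; the labels give no stage, and an effect of genotype itself stays open.

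The libraries can be split into 2 and 2 in only 3 ways, the genotype split included, too few for a share under 0.05. The genotype split gave 5 limma calls, 430 genes with an unadjusted p below 0.01, 354 genes at least 2-fold apart without overlap, and 39.5% of all genes without overlap. The split by replicate number gave 0, 234, 181 and 35.3%, and the third gave 0, 60, 75 and 25.2%.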
